A study of Homo sapiens with 6 samples.

How the data were processed

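Total RNA of 6 H358 cultures was labelled with biotin and hybridised to an Affymetrix human gene array by a genomics core, per the labels' protocols. The deposited values are log2 expression values per probe set, made by the authors with RMA, per the submitters' processing notes. RMA subtracts background, equalises the distribution of intensities across arrays and summarises probes on the log2 scale. Its version, software, settings and probe definitions, and any filter, are not given in the sources used here. RMA forces equal distributions, so a shift of the whole transcriptome between the lines would not show, and background light compresses differences of dim genes. The range of the values (0.866 to 13.7) and similar array medians (4.99, 4.95 and 4.99 for the GFP arrays, 4.99, 4.99 and 5.04 for the TwistER arrays) are those of log2 values that were not centred per gene.

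The groups came from the sample descriptions: H358-GFP (replicates 1 to 3) and H358-TwistER (replicates 1 to 3), both with 100 nM 4OHT for 12 days. Titles call the samples biological replicates and say nothing more of how they were separated, so p-values measure the spread between these samples. All 6 columns of the value table were assigned to a sample, and 0 were left over. No 2 arrays held identical values. The labels give no batch, and no scan data were used.

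The table held 33297 probe sets. Genes were named through the platform annotation supplied with the data: 19460 probe sets had 1 gene symbol, 1754 had several and 12083 were unnamed there. Only those with 1 symbol were used, and a gene with several probe sets (769 genes) took the brightest over all 6 arrays, which gave 18417 genes. Entrez identifiers of 19429 probe sets matched RefSeq's gene table (assembly GRCh38.p14), used for names and chromosomes only, and 0 symbols needed an update. Some probe sets (557) repeat the 6 values of another one. No filter on brightness was applied to the genes tested. Closely related genes of a family can share probes on such an array, and the sources do not say which.

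Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariates, prior degrees of freedom 4.44), with Benjamini-Hochberg adjustment over the 18417 genes and a threshold of 0.05. Folds are powers of the log2 difference, and its SE is limma's. The word rose or fell is used only of genes past this threshold. Gene lists (35, with 998 entries, 966 distinct genes and 915 measured entries) were written from general knowledge. Each was tested with camera at a preset correlation between genes of 0.01, adjusted over the 35 lists, beside the numbers of members past the threshold over all genes and adjusted over the list alone. The same test with an estimated correlation has 4 residual degrees of freedom here. Chromosomes with at least 100 genes were described by the percentile of their median among 10000 random gene sets.

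The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. Named are TWIST1 and ESR1, the markers CDH1, EPCAM, VIM, CDH2, FN1, ZEB1, ZEB2, SNAI1, SNAI2, ERBB3, EGFR and AXL, the 12 largest rises and 12 largest falls at an adjusted p under 0.05 with non-overlapping groups, and up to 4 members of each list with the largest absolute difference. The ranking passed over uncharacterised loci, open reading frames, pseudogenes, olfactory receptors, small and non-coding RNA, and genes sharing a probe set. Together these were 156 genes.

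Alternatives were a second quantile normalization, median centring, cyclic loess, filters at the 25 and 50 percentiles of brightness, the mean of a gene's probe sets, all probe sets without reduction to genes, a trended robust variance, array weights, the replicate number as a block, each array left out in turn, stricter and looser thresholds, limma's treat, an estimated correlation and fry. Numbers of list members that rose or fell without GFP replicate 1, chromosomes without it, and families of gene symbols were added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Simulated data held 18417 genes with the within-group spread of these arrays, and 200 genes were shifted. There limma recovered 97% of genes shifted by 2 on the log2 scale and 79% of those shifted by 1, with 11 calls among unshifted genes. In the same data camera called the shifted list and 0 others. The simulated genes were drawn independently, so this does not show how often camera calls unshifted lists when genes are correlated.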

Results

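Gene expression was measured on 6 microarrays of H358, an established non-small cell lung cancer line of epithelial appearance. The cells stably expressed either green fluorescent protein (GFP, 3 arrays) or TwistER (3 arrays). Constructs of the TwistER kind join the Twist transcription factor to the ligand-binding part of the estrogen receptor, so that 4-hydroxytamoxifen (4OHT) activates the factor. Both lines were given 100 nM 4OHT for 12 days before RNA was taken, which makes the GFP line a control for the drug and for carrying an inserted gene. The submitters' titles describe the GFP arrays as before, and the TwistER arrays as after, epithelial-mesenchymal transition (EMT), the change of epithelial cells to a migratory, fibroblast-like state. The single comparison of the design asks which genes differ between these 2 lines. No TwistER cells without 4OHT were among the arrays. The effect of activating TwistER therefore cannot be told apart from other differences between the lines. Values are log2 expression, 3 arrays per group, and all differences are TwistER minus GFP.

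The 6 arrays separated by line on the first principal component of the 18417 genes tested, which held 57.6% of the variance. Arrays of the same group correlated at r = 0.982 to 0.996 over genes, and no pair across the groups exceeded r = 0.980. GFP replicate 1 stood apart from the other GFP arrays. It correlated with them at r = 0.982 to 0.983, while GFP replicates 2 and 3 correlated with each other at r = 0.996, and it took the opposite side from them on the second component (31.3 against -19.9 and -20.5), which held 24.2% of the variance. Counts of list members are therefore also given without this array where leaving it out moved them by more than 1.5 times. The number of arrays limits the precision of every value.

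**Figure D1:**
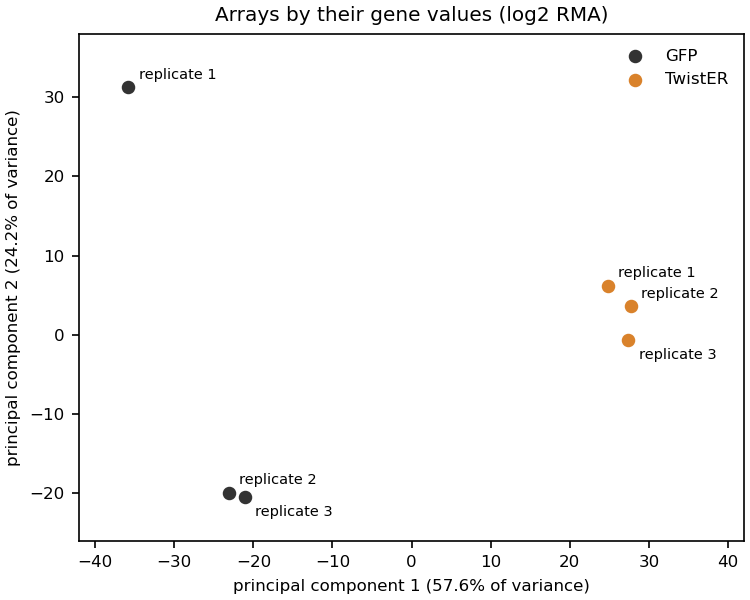
Position of the 6 arrays on the first and second principal components of their log2 gene values, GFP arrays in black and TwistER arrays in orange. The first component (57.6% of the variance) separates the lines, and GFP replicate 1 lies away from the other GFP arrays on the second (24.2%).

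The TwistER cells held far less transcript of E-cadherin and of a set of other epithelial genes than the GFP cells, and more of LOX, DPP4, COL12A1 and other genes. CDH1, which encodes E-cadherin, was 31.9-fold lower in TwistER (log2 difference -4.99 ± 0.23 SE, 3 arrays per group), and the airway serine protease gene TMPRSS11E was 34.3-fold lower (-5.10 ± 0.18). The falls ranked next were in MACC1, a regulator of MET transcription (21.7-fold), AGR2, a protein disulfide isomerase of secretory epithelia (21.5-fold), and GRHL2, a transcription factor that maintains epithelial identity (21.1-fold). The largest rise was in RUNX1T1, a transcriptional co-repressor, at 19.8-fold (4.31 ± 0.14). It was followed by the collagen cross-linking enzyme LOX (13.9-fold, 3.80 ± 0.13), the surface peptidase DPP4 (13.5-fold, 3.75 ± 0.10), the fibril-associated collagen COL12A1 (13.3-fold, 3.73 ± 0.13) and the membrane protein TMEM47 (13.1-fold, 3.71 ± 0.18).

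Of the 18417 genes, 1627 (8.83%) changed at a Benjamini-Hochberg adjusted p under 0.05 in limma, 870 upward and 757 downward, and in all 1627 the 3 TwistER arrays lay outside the range of the 3 GFP arrays. At least 2-fold changes numbered 504, with 305 rises and 199 falls. At least 8-fold, 8 genes rose and 15 fell. Groups did not overlap in 5237 genes (28.4%), where chance gives 10%. The other genes among the 12 largest rises were PTGS2, the inducible cyclooxygenase (11.4-fold), TNFAIP6, a hyaluronan-binding secreted protein (10.7-fold), the kinase gene NRK (10.1-fold), GGTA1 (7.96-fold), the activin subunit INHBA (7.73-fold), COL14A1 (7.65-fold) and NDNF (7.60-fold). Among the 12 largest falls were also RAB25, a small GTPase of apical recycling (15.5-fold), TSPAN1 (12.8-fold), MAL2 (11.7-fold), FGFBP1 (10.7-fold), MYO5C (9.82-fold), EPCAM (9.73-fold) and ANKRD22 (9.62-fold). TNFAIP6 and GGTA1 in the GFP arrays, and TMPRSS11E, AGR2 and ANKRD22 in the TwistER arrays, had a mean in the lower quartile of the arrays, where background light compresses differences. The number of changed genes depended on which arrays were used: it was 2773 without GFP replicate 1, which shared 1609 genes with the 1627, 1063 without GFP replicate 2, and 912, 831 and 935 without TwistER replicates 1, 2 and 3.

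**Figure D2:**
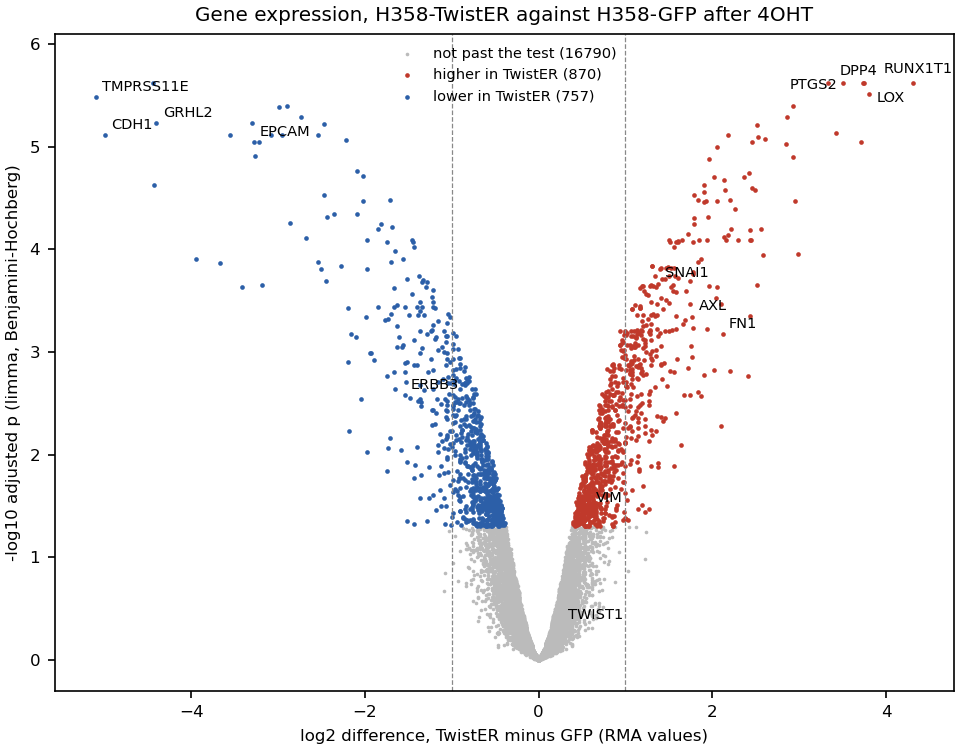
Each point is a gene, with its log2 difference between TwistER and GFP (RMA values, 3 arrays per group) on the horizontal axis and -log10 of the limma adjusted p on the vertical axis. Points in red (870) and blue (757) passed an adjusted p under 0.05, and dashed lines mark 2-fold. CDH1 and TMPRSS11E lie farthest to the left, RUNX1T1 farthest to the right, and TWIST1 lies among the genes that did not pass.

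Many epithelial genes fell. Of 33 measured genes of the epithelial surface and keratins, 25 fell and 0 rose, with a median log2 difference of -1.39. Examples were AGR2, RAB25 (-3.95 ± 0.30), TSPAN1 (-3.67 ± 0.29) and MAL2 (-3.55 ± 0.16), the last a component of apical transport. Adjusted over the list alone, 28 fell. limma's camera gave an adjusted p = 9.13e-26 for this list with its preset correlation, and an adjusted p = 0.132 with an estimated correlation. Of 26 epithelial junction genes, 15 fell and 0 rose, with a median of -0.77, and 19 fell when adjusted over the list alone. Besides CDH1 these included EPCAM (-3.28 ± 0.16), the desmosomal cadherin DSC2 (-2.74 ± 0.11) and the tight junction adhesion protein CXADR (-1.74 ± 0.13). The camera adjusted p was 1.76e-16, and adjusted p = 0.132 with an estimated correlation. Of 16 genes listed from general knowledge as regulators of epithelial identity, 7 fell and 0 rose (median -0.64), or 10 and 1 adjusted over the list alone. Such a role was not tested here for any of them. GRHL2 (-4.40 ± 0.18) led this group, followed by EHF, an ETS factor of epithelia (-2.05 ± 0.29), RBM47, an RNA-binding regulator of splicing (-1.81 ± 0.12), and ZNF165 (-1.66 ± 0.16). EHF had a TwistER mean of 2.63, in the lower quartile of the arrays, where background light compresses differences. The camera adjusted p of the regulator list was 1.22e-06, and adjusted p = 0.272 with an estimated correlation. GFP replicate 1 was itself lower than the other GFP arrays in these 3 lists, by medians of -0.20, -0.29 and -0.32, and without it 28, 18 and 10 members fell.

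Few transcripts of lung epithelial identity passed the test. Of 31 measured genes of the alveolar, club and other airway lineages, 2 fell and 0 rose, with the same counts adjusted over the list alone, a median of -0.09 and a camera adjusted p of 0.0744 in limma. The members that fell were FOXA2, a forkhead factor of the lung endoderm (-0.96 ± 0.17, adjusted p = 0.00916), and the aldehyde dehydrogenase ALDH3A1 (-0.50 ± 0.11, adjusted p = 0.0283). ALDH3A1 lost its call without any array other than GFP replicate 1, with a highest adjusted p of 0.129. The related factor FOXA1 had a difference of -0.35 ± 0.10 that did not pass (adjusted p = 0.0752), and without GFP replicate 1 it was -0.36 and passed (limma adjusted p = 0.0428), so that 3 members of the list fell there.

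Several transcription factors known to drive EMT rose, 6 of the 19 measured. SNAI1, a repressor of CDH1, was 2.61-fold higher (1.38 ± 0.12), ZEB2 was 2.50-fold higher (1.32 ± 0.13), and ZEB1 was 2.12-fold higher (1.09 ± 0.14), each with a limma adjusted p of 0.00221 or less. SNAI2 rose 1.73-fold from an already high level, with a mean of 10.24 ± 0.27 in GFP and 11.03 ± 0.08 in TwistER (SD, n = 3). Its limma adjusted p of 0.0117 was lost without TwistER replicate 1 or 3, with a highest value of 0.0613. In this list 6 rose, 0 fell and 13 did not pass, or 7 rose and 0 fell adjusted over the list alone, with a median of 0.19. In camera, the list's adjusted p was 0.000179, and adjusted p = 0.274 with an estimated correlation. GFP replicate 1 was below the other GFP arrays in this list by a median of -0.19, and without it the preset camera adjusted p was 0.00514.

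The human genes to which the name of the construct points, TWIST1 and ESR1, showed no difference past the test. TWIST1 read 6.21, 6.20 and 6.62 in the GFP arrays and 6.30, 6.67 and 6.84 in the TwistER arrays, a difference of 0.27 ± 0.17 that did not pass in limma (adjusted p = 0.457, 95% interval -0.13 to 0.66). ESR1 read 4.20 ± 0.18 in GFP and 4.43 ± 0.07 in TwistER (SD, n = 3), and its difference of 0.23 ± 0.12 did not pass either (limma adjusted p = 0.338). The labels give neither the species of the inserted sequence nor the part of it that these probes cover, so the values do not check the labels of the arrays.

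Part of the mesenchymal genes were higher in TwistER, and some of them were already high in GFP. Of 31 measured mesenchymal markers, 12 rose and 1 fell, with a median of 0.31, and 13 rose and 1 fell adjusted over the list alone. Fibronectin (FN1) rose 4.34-fold (2.12 ± 0.22), the membrane-anchored protease inhibitor RECK 2.98-fold (1.58 ± 0.23), the matrix glycoprotein SPARC 2.98-fold (1.57 ± 0.13) and the collagen receptor MRC2 2.55-fold (1.35 ± 0.22). Vimentin (VIM) was abundant in both lines, at 10.82 ± 0.19 in GFP and 11.41 ± 0.16 in TwistER (SD, n = 3), and rose 1.51-fold (limma adjusted p = 0.0332). That call was lost without any array other than GFP replicate 1, with a highest limma adjusted p of 0.144 and a VIM difference of 0.48 to 0.68. N-cadherin (CDH2) was likewise high in both, and its difference of 0.36 ± 0.14 did not pass (adjusted p = 0.166). The list's camera adjusted p in limma was 7.91e-07, and adjusted p = 0.154 with an estimated correlation.

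**Figure D3:**
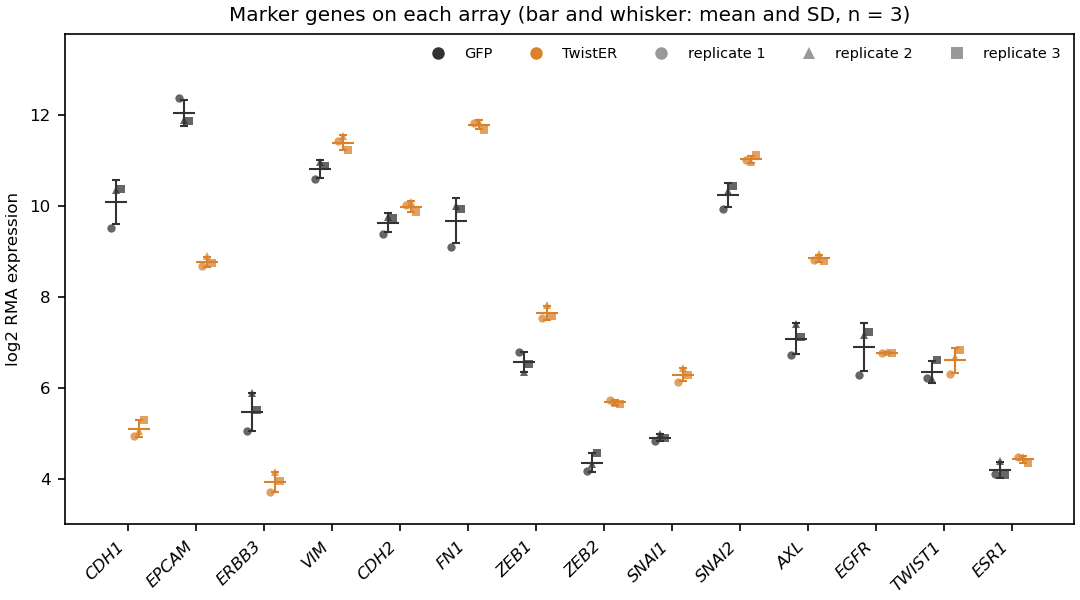
log2 expression of 14 marker genes on each of the 6 arrays, GFP in black and TwistER in orange, with symbols for the replicates and bars and whiskers for the mean and SD of 3 arrays. CDH1, EPCAM and ERBB3 lie lower in TwistER, FN1, ZEB1, ZEB2, SNAI1, SNAI2, AXL and VIM lie higher, and EGFR, TWIST1 and ESR1 overlap between the groups.

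Of 40 measured collagen and matrix genes 16 rose, 2 fell and 22 did not pass, with a median of 0.28 and the same counts of rises and falls adjusted over the list alone. Without GFP replicate 1, 16 rose and 4 fell. Besides LOX and COL12A1, the microfibril protein FBN1 rose 4.61-fold (2.21 ± 0.15) and CCDC80 4.52-fold (2.18 ± 0.10). The camera adjusted p was 6.86e-07, and adjusted p = 0.132 with an estimated correlation. Among 17 fibroblast markers, which stand for a cell type that a culture could hold, 5 rose and 1 fell, with the same counts adjusted over the list alone, a median of 0.08 and a camera adjusted p of 0.0881 in limma. COL3A1 rose 4.39-fold (2.13 ± 0.15), FBLN1 3.60-fold (1.85 ± 0.13) and PDGFRA 2.01-fold (1.01 ± 0.13), whereas the proteoglycan gene LUM fell 3.09-fold (-1.63 ± 0.18). Of 28 matrix proteases and their inhibitors, 5 rose and 1 fell, or 9 and 1 adjusted over the list alone, with a median of 0.10. The metalloproteases ADAMTS1 (1.49 ± 0.12) and ADAMTS12 (1.43 ± 0.22) and the inhibitor SERPINE2 (1.41 ± 0.17) rose, and the epithelial serpin SERPINB5 fell (-1.21 ± 0.12). This list was called at a camera adjusted p = 0.0480, with an adjusted p = 0.461 with an estimated correlation. It lost the call without GFP replicate 1 (camera adjusted p = 0.202), TwistER replicate 2 (0.0938) or TwistER replicate 3 (0.0604), and 5 rose and 4 fell without GFP replicate 1.

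Some genes of TGF-beta and BMP signalling, and some targets of actin dynamics and the co-activator YAP, were also higher. Of 44 TGF-beta and BMP genes, 14 rose and 1 fell, with a median of 0.23, or 17 and 3 adjusted over the list alone, and 15 and 4 without GFP replicate 1. INHBA rose 7.73-fold (2.95 ± 0.18), ID2, an inhibitor of helix-loop-helix factors and BMP target, 5.15-fold (2.36 ± 0.13), and the BMP signal transducers SMAD9 and SMAD1 3.29-fold and 2.85-fold (1.72 ± 0.21 and 1.51 ± 0.11). In camera, the list's adjusted p was 2.15e-06, and adjusted p = 0.161 with an estimated correlation. Of 31 actin and YAP target genes 10 rose and 2 fell, with a median of 0.31, or 15 and 2 adjusted over the list alone. They included CRIM1 (1.42 ± 0.18), the matricellular protein CCN2 (1.23 ± 0.14), the myosin light chain MYL9 (1.19 ± 0.12) and the tropomyosin TPM2 (0.93 ± 0.13). This list had a camera adjusted p of 1.54e-06, and adjusted p = 0.161 with an estimated correlation. Of 14 smooth muscle markers, ACTA2, smooth muscle actin, was the 1 that rose (1.07 ± 0.16), also adjusted over the list alone, 0 fell, and the list had a median of -0.05, a mean of 0.06 and a camera adjusted p of 0.957 in limma.

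Receptor genes moved in both directions. ERBB3, a kinase-impaired partner of the EGF receptor family, fell 2.91-fold (-1.54 ± 0.21), its family's ligands EREG and TGFA fell 7.73-fold (-2.95 ± 0.13) and 1.95-fold (-0.96 ± 0.15), and LRIG3 rose 2.25-fold (1.17 ± 0.11). EGFR had a difference of -0.13 ± 0.23 with a limma adjusted p of 0.824, and without GFP replicate 1 the difference was -0.43, with a limma adjusted p of 0.0162. Of 17 ERBB receptors and ligands 2 rose and 3 fell, the same counts as adjusted over the list alone, and 2 and 5 without GFP replicate 1, with a median of -0.07 and a camera adjusted p of 0.373 in limma. Among other receptor kinases and their ligands, AXL, often high in mesenchymal tumour cells, rose 3.40-fold (1.77 ± 0.17) and the ephrin receptor EPHA4 5.62-fold (2.49 ± 0.14), while FGFBP1, a carrier of fibroblast growth factors, fell 10.7-fold (-3.42 ± 0.30). In that list of 43, 7 rose and 2 fell, or 10 and 3 adjusted over the list alone, and 8 and 6 without GFP replicate 1, with a median of 0.05 and a camera adjusted p of 0.218 in limma. Of 19 integrins 3 rose and 4 fell, also adjusted over the list alone, with a median of -0.03 and a camera adjusted p of 0.555 in limma. ITGB6, an epithelial integrin that activates latent TGF-beta, fell 7.95-fold (-2.99 ± 0.12), and the collagen receptor subunit ITGA2 fell 2.35-fold (-1.23 ± 0.13).

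Components and outputs of the pathways below these receptors were mixed too. Of 31 PI3K-AKT components 2 rose and 1 fell, or 3 and 1 adjusted over the list alone, and 3 and 4 without GFP replicate 1, with a median of 0.02 and a camera adjusted p of 0.834 in limma. DEPTOR, an inhibitor of mTOR, rose 3.21-fold (1.68 ± 0.23), and the regulatory subunit PIK3R3 fell 2.06-fold (-1.04 ± 0.10). Of 27 genes read as output of the ERK pathway 4 rose and 2 fell, or 4 and 3 adjusted over the list alone. EGR1, an immediate early factor, rose 2.64-fold (1.40 ± 0.15), while PHLDA1 and the ERK phosphatase DUSP4 fell 2.33-fold (-1.22 ± 0.11) and 1.84-fold (-0.88 ± 0.12). The ERK list had a median of -0.12, a mean of 0.01 and a camera adjusted p of 0.727 in limma. Without GFP replicate 1, 4 of its members rose and 8 fell.

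Some interferon response genes were higher in TwistER and some NRF2 targets lower. Of 33 interferon response genes 10 rose and 1 fell, with a median of 0.12, or 15 and 2 adjusted over the list alone. The membrane protein IFITM1 rose 2.47-fold (1.31 ± 0.10), the chemokine CXCL10 2.47-fold (1.30 ± 0.16), IFI44L 2.19-fold (1.13 ± 0.16) and the immunoproteasome subunit PSMB9 2.10-fold (1.07 ± 0.13). The camera adjusted p was 0.00261, and adjusted p = 0.132 with an estimated correlation, and the list lost its call among genes above the median brightness (0.252). Of 33 inflammatory cytokine and NF-kB target genes 2 rose and 1 fell, also adjusted over the list alone, with a median of -0.03, a mean of 0.04 and a camera adjusted p of 0.957 in limma. PTGS2 rose 11.4-fold (3.51 ± 0.11) and CCL5 2.55-fold (1.35 ± 0.16), and the cytokine IL18 fell 5.83-fold (-2.54 ± 0.20). Of 21 targets of NRF2, the regulator of the antioxidant response, 5 fell and 0 rose, with a median of -0.39, or 6 and 1 adjusted over the list alone. Without GFP replicate 1, 9 fell and 1 rose. Malic enzyme ME1 fell 3.17-fold (-1.67 ± 0.14), GCLC, the catalytic subunit for glutathione synthesis, 2.08-fold (-1.06 ± 0.11), and thioredoxin reductase TXNRD1 1.78-fold (-0.84 ± 0.14). In camera, the list's adjusted p was 0.00240, and adjusted p = 0.215 with an estimated correlation.

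Some genes of DNA replication and a few replication-dependent histones were lower, by less than 2-fold each. Of 30 DNA replication genes 7 fell and 0 rose, also adjusted over the list alone, with a median of -0.20. They included the factor E2F8 (-0.71 ± 0.13), the cyclins CCNE2 (-0.70 ± 0.15) and CCNE1 (-0.56 ± 0.13) and the ribonucleotide reductase subunit RRM2 (-0.57 ± 0.11). The camera adjusted p was 0.00126, and adjusted p = 0.299 with an estimated correlation, and GFP replicate 1 was below the other GFP arrays in this list too, by a median of -0.20, and without it 11 fell. Each of these 4 genes lost its call without TwistER replicate 1 or TwistER replicate 3, RRM2, CCNE2 and CCNE1 also without TwistER replicate 2, RRM2 and CCNE1 also without GFP replicate 2, and CCNE1 also without GFP replicate 3, with highest limma adjusted p values of 0.0547 for E2F8, 0.114 for CCNE2, 0.133 for CCNE1 and 0.0703 for RRM2. Of 20 histone genes 2 fell and 0 rose, with a median of -0.27, or 5 and 0 adjusted over the list alone and again without GFP replicate 1. Those past the test over all genes were H1-5 (-0.74 ± 0.11) and H2AC6 (-0.47 ± 0.10), the latter called only with all arrays or without GFP replicate 1, with a highest limma adjusted p of 0.105 otherwise. In camera, the list's adjusted p was 0.000132, and adjusted p = 0.132 with an estimated correlation. Of 30 genes of the G2/M phase 0 rose and 0 fell, also adjusted over the list alone, with a median of -0.10 and a camera adjusted p of 0.0579 in limma, or 0.0430 without GFP replicate 1, where 4 fell. With an estimated correlation and all arrays, the camera adjusted p of the G2/M list was 0.290. Its members differed in sign: the kinesin gene KIF20A had the largest absolute difference (0.61 ± 0.25, limma adjusted p = 0.194), and CCNB1, the mitotic cyclin B1, had -0.40 ± 0.11 (limma adjusted p = 0.0637). Of 24 cell cycle inhibitors and p53 targets 1 rose and 1 fell, or 3 and 1 adjusted over the list alone, and 4 and 1 without GFP replicate 1, with a median of -0.02, a mean of 0.06 and a camera adjusted p of 0.809 in limma. TP53INP1 rose 2.25-fold (1.17 ± 0.17).

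The other lists were not called as groups by limma's camera, and counts in this paragraph are the same adjusted over the list alone unless both are given. Of 15 stem-like markers 4 rose and 4 fell, or 5 and 5 adjusted over the list alone (median 0.06, camera adjusted p = 0.957): the R-spondin receptor gene LGR5 (0.96 ± 0.14) and the intermediate filament nestin, NES (0.90 ± 0.13), rose, and ALDH1A3 (-1.30 ± 0.11) and KLF4 (-0.68 ± 0.11) fell. LGR5 had a GFP mean of 2.98, in the lower quartile of the arrays, where background light compresses differences. Of 41 Wnt and Notch genes 4 rose and 4 fell, or 5 and 5 adjusted over the list alone (median -0.02, camera adjusted p = 0.957), with the Wnt antagonist DKK1 higher (1.40 ± 0.11) and the receptor ligase RNF43 lower (-1.19 ± 0.13). Of 23 genes listed under cholesterol synthesis 1 rose and 2 fell (median -0.10, camera adjusted p = 0.141). The fatty acid desaturase SCD, counted in this list, was lower (-0.81 ± 0.13), and SC5D was the one that rose (0.81 ± 0.16). SC5D lost its call without GFP replicate 2 or 3 or TwistER replicate 1 or 2. Of 30 hypoxia and glycolysis genes 2 rose and 2 fell (median -0.05, camera adjusted p = 0.431), with the prolyl hydroxylase EGLN3 lower (-1.07 ± 0.12) and P4HA2 higher (1.38 ± 0.26). P4HA2 lost its call without any of the TwistER replicates. GFP replicate 1 was below the other GFP arrays by medians of -0.27 and -0.33 in these 2 metabolic lists, and without it both were called downward, at camera adjusted p = 0.0345 and 0.00340, with 7 and 10 members that fell. With an estimated correlation and all arrays, their camera adjusted p values were 0.286 and 0.921. Of 24 genes of the unfolded protein response 1 rose and 1 fell (median 0.01, camera adjusted p = 0.966), VLDLR was the one that rose (0.77 ± 0.13), and 1 rose and 2 fell without GFP replicate 1. Of 19 estrogen responsive genes, included because both lines received 4OHT, 2 rose and 2 fell (median 0.07, mean -0.04, camera adjusted p = 0.965), among them IGFBP4 (0.70 ± 0.12) and MYB (-0.77 ± 0.15), and 2 rose and 4 fell without GFP replicate 1. Of 17 neuroendocrine and neuronal markers 1 rose and 2 fell (median -0.03, camera adjusted p = 0.809), UCHL1 by -0.89 ± 0.14, and 2 rose and 2 fell without GFP replicate 1.

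Markers chosen for cell types foreign to the culture, and reference genes, were counted in the same way. Of 20 leukocyte markers 0 rose and 1 fell, or 0 and 0 adjusted over the list alone, and 1 and 2 without GFP replicate 1 (median 0.07, limma camera adjusted p = 0.957). The 1 that fell was LCP1 (-0.41 ± 0.10), which was abundant in both lines, with means of 10.41 in GFP and 10.00 in TwistER. Its call was lost without any array other than GFP replicate 1. Of 15 endothelial markers 2 rose and 0 fell, also adjusted over the list alone (median 0.07, limma camera adjusted p = 0.281), with the VEGF receptor KDR 3.47-fold higher (1.79 ± 0.12). Of 38 ribosomal protein genes 0 rose and 0 fell, also adjusted over the list alone, with a median of 0.00, a mean of 0.01 and a limma camera adjusted p of 0.957 with a downward sign. Of 15 reference genes 0 rose and 2 fell, also adjusted over the list alone, and 0 and 4 without GFP replicate 1 (median -0.02, limma camera adjusted p = 0.428). These were YWHAZ (-0.42 ± 0.10) and TFRC, the transferrin receptor (-0.42 ± 0.11). Both lost their calls after a second quantile normalization (-0.35 and -0.34) or cyclic loess (-0.34 and -0.33), with the replicate block, and without any array other than GFP replicate 1. Some abundant transcripts were low in GFP replicate 1 alone: ACTB read 9.88 there against 11.33 and 11.27 in the other GFP arrays, and RPL8 read 9.40 against 11.44 and 11.38.

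**Figure D4:**
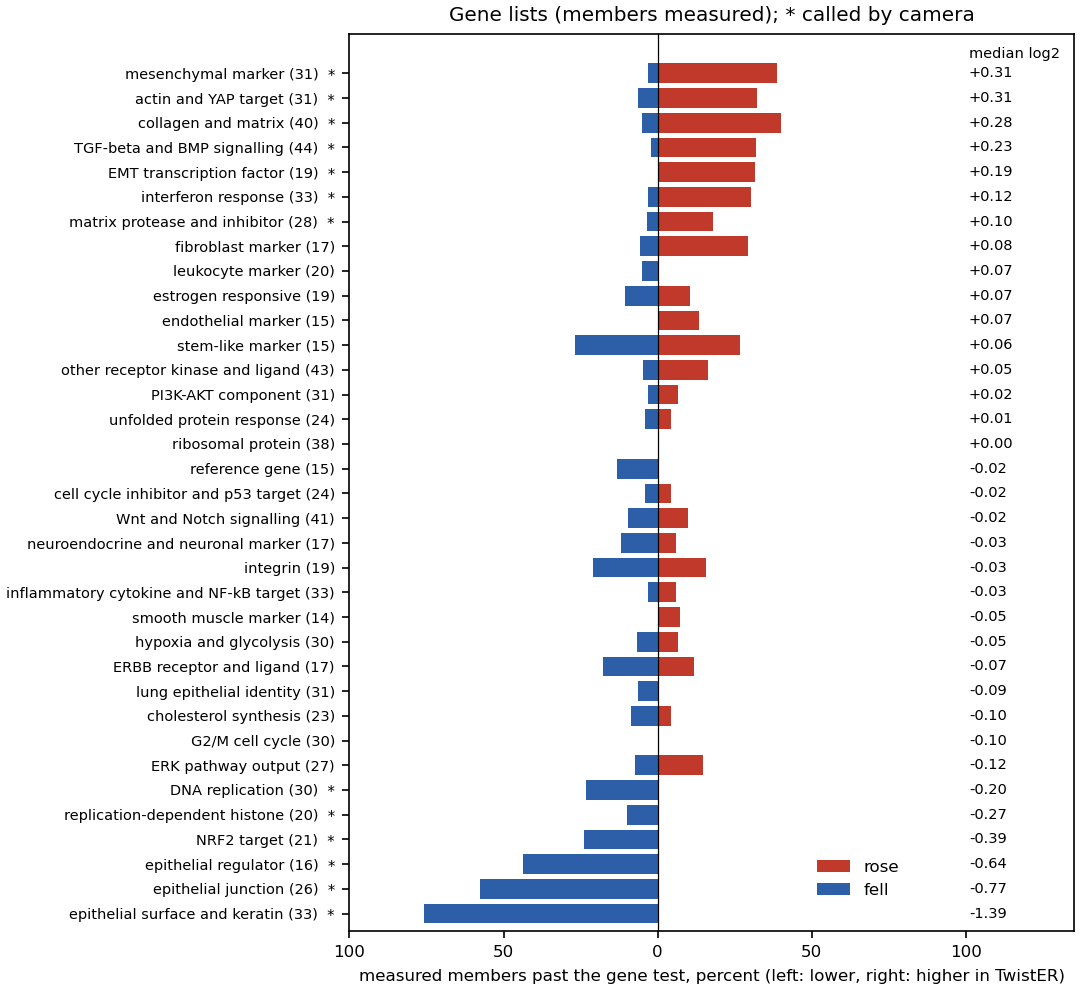
Share of the measured members of each of the 35 gene lists that passed the limma test, higher in TwistER to the right in red and lower to the left in blue, with the number measured in brackets and the median log2 difference at the right edge. Stars mark the 13 lists called by camera with its preset correlation, none of which held with an estimated correlation. The 3 epithelial lists extend farthest to the left.

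Of the 35 lists 13 were called, 7 upward and 6 downward. With an estimated correlation 0 lists passed, the lowest limma camera adjusted p being 0.132. limma's fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, called 20 lists, and 34 when either direction counted.

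Median log2 differences of whole chromosomes lay between -0.031 and 0.034 over 23 chromosomes. Of these, 6 had a median outside the 2.5 to 97.5 percentile range of 10000 random gene sets of the same size, where 1.15 would be expected by chance. Chromosome 8 had the lowest median (-0.031, 638 genes) and chromosome X the highest (0.034, 694 genes). Among genes above the median brightness the medians were wider apart, from -0.128 (chromosome 13) to 0.026 (chromosome X), around -0.027 for all genes of that setting. Random sets treat genes as independent, so these percentiles describe the arrays and test no copy number.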

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

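All tests of explanations in this part were chosen after the results were seen, while the splits of the arrays were planned. Probe sets that the annotation left unnamed, which no gene comparison used, held signal above the GFP arrays: 30 rose at least 2-fold in TwistER (adjusted over all probe sets in limma) and 25 fell, with a largest rise of 4.60 and a largest fall of -4.08 on the log2 scale. Among probe sets with several gene symbols, also left out, 7 rose at least 2-fold and 12 fell.

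GFP replicate 1 stood apart from the other GFP arrays over the whole transcriptome. The TwistER difference explained at most 1.78% of the variance over genes of its deviation, against 58.3% for a TwistER array put in its place. This argues against a shift of that culture toward the TwistER profile as the main source of the deviation. A small shift would explain little variance too, so it stays open. The genes lowered at least 2-fold in TwistER deviated in GFP replicate 1 by a median of -0.19, and the raised ones by 0.05. With TwistER compared with GFP replicate 2 or 3 alone and GFP replicate 1 set against the array not used, the 366 genes raised at least 2-fold implied a median share of 1.89% TwistER RNA in it (95% bootstrap interval up to 3.12), and the 252 lowered at least 2-fold implied 23.0% (from 9.25), so that admixed TwistER cells cannot give both. Probes of small nuclear and nucleolar RNA lay 0.35 higher relative to protein-coding genes in this array than in the other 2 GFP arrays. The other 5 arrays, each set against the other 2 of its group, lay at -0.20 to 0.05. Of these, GFP replicates 2 and 3 (-0.14 and -0.20) are not independent, since GFP replicate 1 enters their comparison. The TwistER arrays lay at -0.06 to 0.05. A difference in RNA preparation, amplification or labelling of GFP replicate 1 could give such a shift. A biological difference of that culture stays open, since the labels record neither culture nor preparation.

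TWIST1 and ESR1 did not pass the test, although the label TwistER was read here as pointing to both. A single array with the wrong group label is argued against, since each array correlated better with its own group than with the other, by at least 0.0104. The 95% interval of the TWIST1 difference reached up to 0.66 on the log2 scale with all arrays, and the difference itself moved from 0.27 to between 0.15 (without TwistER replicate 3) and 0.42 (without TwistER replicate 1), or 0.40 without GFP replicate 3. An insert that these probes do not read, of another species or limited to the coding part, cannot be told apart from a low level of the construct, because the labels do not describe the insert.

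The rise of collagen and matrix genes could come from fibroblasts mixed into the TwistER cultures. Of the 5 abundant fibroblast transcripts, 3 had a 95% interval that reached 0 or lay below it: COL1A2 (-0.03 ± 0.12), DCN (0.01 ± 0.12) and LUM (-1.63 ± 0.18), while COL1A1 rose by 0.54 ± 0.13 and COL3A1 by 2.13 ± 0.15. This argues against admixture, but mainly through COL1A2. DCN read 2.37 in both lines, in the lower quartile of the arrays, where background light hides differences. LUM read 7.62 in GFP, so a fall in the line's own cells could hide LUM from fibroblasts. Without GFP replicate 1, 16 members rose and 4 fell, with a camera adjusted p of 6.01e-06, which argues against that array as the source. As a hypothesis found and tested on the same data, the matrix transcripts may therefore be made by the TwistER cells themselves.

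The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In each case 1 split, the real one, gave a result as large: 1627 changed genes against a highest of 0 in the others, 504 genes changed at least 2-fold against 0, and 13 gene lists against 9. The other splits had 3 to 9 lists called although 0 genes changed in them, so a camera call at the preset correlation did not need a changed gene. Each of these splits still held the lines unequally on its sides, so part of the difference between the lines remained in them.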

How the results depend on the processing

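The test of chromosomes without GFP replicate 1 was chosen after seeing the data, and the others here were planned. Of 1742 values of the 118 called named genes under alternatives, 1636 kept direction and call, 106 lost the call and 0 reversed. Leaving out or weighting arrays could not reverse a called gene, since its groups do not overlap, nor could a change of the variance model. The 1627 changed genes became 3268 (1551 raised, 1717 lowered) with array weights, which gave GFP replicate 1 a weight of 0.19, 807 at an adjusted p under 0.01, and 831 (without TwistER replicate 2) to 2773 (without GFP replicate 1) when an array was left out. Under the other alternatives they numbered 1142 (all probe sets) to 1743. The 504 genes of at least 2-fold became 291 with treat against 1.5-fold and 1236 with a 1.5-fold minimum, and stayed between 378 and 530 otherwise. Same-numbered arrays deviated together at r = 0.14, 0.02 and 0.16 over genes, and GFP replicates 1 and 3 correlated best with the TwistER array of their own number but GFP replicate 2 with TwistER replicate 3, so the data do not show that the numbers pair the samples. With the replicate block 1592 genes changed (840 raised, 752 lowered) and 5 of the 118 named genes lost the call. The count of 13 lists became 0 with an estimated correlation, 20 with fry in 1 direction and 34 with fry in either. With an estimated correlation, which leaves 4 residual degrees of freedom, adjusted p was 0.132 for epithelial surface, epithelial junction, collagen, interferon and histone lists, 0.154 for mesenchymal, 0.161 for TGF-beta and for actin and YAP, 0.215 for NRF2, 0.272 for epithelial regulators, 0.274 for EMT factors, 0.299 for DNA replication and 0.461 for proteases. Other lost calls were DNA replication with fry (0.0543), interferon above median brightness (0.252) and proteases with quantile normalization (0.0559), cyclic loess (0.0620), the mean of probe sets (0.0724), array weights (0.143) and 3 of the 6 fits with an array left out (0.0224 to 0.202 over all 6). The estimated correlation between genes was -0.006 in the interferon list and 0.006 in the histone list, below the preset 0.01. A higher correlation therefore does not explain why these lists lost their calls with an estimated correlation. In the other called lists it was 0.040 to 0.339, where correlation and the few degrees of freedom cannot be told apart. The cause of the lost calls was otherwise not tested except where fewer arrays or genes entered. Direction reversed, among genes that did not pass, with an array left out for EGFR (-0.43 to 0.04), TAGLN (-0.37 to 0.04), ACTB (-0.06 to 0.66), RPL13 (-0.03 to 0.64) and RPL8 (-0.28 to 0.74), for RPL8 with array weights (-0.18), and for RPL29 with the mean of probe sets (0.06). Chromosomes outside the random range numbered 6, 9 above median brightness and 8 without GFP replicate 1. Chromosomes 1, 2, 8, 13 and X lay outside both with all genes and above median brightness. Only chromosomes 1, 8 and X lay outside both with all arrays and without GFP replicate 1. Chromosome 4 went from percentile 0.81 to 94.47 without that array. TWIST1 and ESR1 passed in none of the alternatives run. Dim genes limit what can be seen, since background light hides differences near the floor.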

Other observations

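The families of gene symbols in this part were chosen after seeing the data, as were their tests. Genes sharing a symbol stem formed 479 families of at least 6 genes, of which 12 were called by limma's camera with the preset correlation and 0 with an estimated correlation (adjusted p = 0.905 for each of the 12). Some mitochondrial ribosomal protein genes were lower in TwistER. Of 48 genes of the large subunit (MRPL) 5 fell and 0 rose, with a median of -0.24 and a camera adjusted p of 0.000274, and 15 fell without GFP replicate 1. MRPL19 fell by 0.57 ± 0.11 and MRPL24 by 0.54 ± 0.10 on the log2 scale. Of 26 small subunit genes (MRPS) 4 fell and 0 rose (median -0.24, camera adjusted p = 0.00450), led by MRPS17 (-0.76 ± 0.16) and MRPS12 (-0.74 ± 0.13), and 10 fell without GFP replicate 1. Of 11 NDUFB subunits of respiratory complex I, 2 fell and 0 rose (median -0.40, camera adjusted p = 0.0180), NDUFB9 by -0.73 ± 0.12 and NDUFB4 by -0.50 ± 0.10. The other families of this complex were not called: 1 of 12 NDUFA, 1 of 6 NDUFS and 0 of 7 NDUFAF genes fell (limma camera adjusted p = 0.0974, 0.445 and 0.119, medians -0.22, -0.10 and -0.34). Without GFP replicate 1, 3 NDUFB, 1 NDUFA, 2 NDUFS and 1 NDUFAF genes fell, and the difference between these families was not tested. The cytosolic ribosomal proteins had a median of 0.00.

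Some protocadherin families were called upward, while the alpha cluster was not, a difference that was not itself tested. Of 12 alpha protocadherins (PCDHA) 0 rose and 0 fell (median 0.15, camera adjusted p = 0.388 in limma). Of 18 clustered beta protocadherins (PCDHB) 6 rose and 0 fell, with a median of 0.47 and a camera adjusted p of 0.00142, and 8 rose without GFP replicate 1. PCDHB10 rose 2.14-fold (1.10 ± 0.11) and PCDHB5 2.07-fold (1.05 ± 0.17). These genes are close in sequence, and probes that they share were not told apart, so 6 is uncertain as a number of separate genes. Without GFP replicate 1 the camera adjusted p of the family was 0.000131. Of 11 other protocadherins (PCDH) 4 rose and 0 fell (median 0.29, camera adjusted p = 0.00450), including PCDH18 (1.66 ± 0.17) and PCDH20 (1.36 ± 0.14). Of 7 genes of the butyrophilin family (BTN) of surface proteins, 4 rose and 0 fell (median 0.58, camera adjusted p = 0.00450), with BTN3A3 at 0.78 ± 0.18 and BTN3A2 at 0.72 ± 0.11. GFP replicate 1 was below the other GFP arrays in this family by a median of -0.41. Without that array 4 still rose, at a camera adjusted p of 0.0183. The other families called were COL, IFI, ZKSCAN and SMAD upward and PSMA and CCT downward, of which ZKSCAN and PSMA lost the call without GFP replicate 1 (camera adjusted p = 0.0503 and 0.0575).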
